A study of Homo sapiens with 6 samples.

How the data were processed

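RNA was measured by sequencing in IMR-32 cells, an established human neuroblastoma line with amplified MYCN, that stably carried an empty lentiviral vector (pLenti 5). Per the labels, 3 libraries came from cells kept for 16 days in 2.5 µM BrdU, a thymidine analogue that dividing cells build into their DNA, and 3 libraries came from untreated cells. The groups were taken from the treatment label, since the extraction text is the same for all 6 libraries. That label gives no time in culture for the untreated cells. Per the labels' protocols, total RNA was isolated with Trizol, and 3 µg was made into libraries with a directional Illumina kit. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

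The table used here is the authors' own comparison of the 2 groups. Per the submitters' processing notes, the authors used bcl2fastq 2.20, HISAT, HTSeq and edgeR with the genome build hg38. The versions of HISAT, HTSeq and edgeR, the gene annotation, the low-count filter, the normalization factors, the strand setting of the counting and the design of the fit are not given in the sources used here. Per the file headers, each of 15108 rows gives a gene symbol, a log2 fold change, a mean log2 CPM (reads scaled to the library total) over the libraries, an F statistic, a p-value and an FDR. The base of the log2 CPM column was checked on the deposited values: 2 to the power of these values sums to 1.0037e+06, close to the total that base 2 requires. The base of the fold change column was taken as 2 and was not checked. The authors' deposited FDR equals the Benjamini-Hochberg adjustment of their p-value over all rows, with a largest difference of 1.42e-15. Values per library were not used here, so the depth of each library is unknown, no interval that needs it is given, and the error behind each fold change is its adjusted p.

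The direction of the authors' deposited log2 fold change is not stated in the header or the labels. It was read as positive where a gene was higher in the BrdU-differentiated cells, because textbook genes of neuronal differentiation (such as TH, DBH, NTRK2, RET, GAP43 and NEFL) have positive values while MYCN, LIN28B and DNA replication genes have negative ones. The name of the comparison gives the untreated group (EV) before the BrdU-differentiated one (dEV) and does not say which was subtracted. Taken as EV minus dEV, that order would give the opposite sign. If the sign ran the other way, every "higher" and "lower" in the text would swap together. The catecholamine, neurite, neurotrophic receptor, DNA replication, MYCN target and early developmental lists contain these genes and are therefore not independent evidence of the direction.

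The denominator degrees of freedom behind each test were recovered by solving the F distribution with 1 numerator degree of freedom for the value that turns the authors' deposited F into their p-value. This gave a value for 14377 rows, between 15.13 and 15.30 for 14094 of them. For 140 rows it lay in that range lowered by 2 and widened by 0.001 at each end. A reduction by 2 is what the authors' tool, edgeR, applies when all libraries of a group of 3 hold no reads of the gene. These rows are called genes recovered as having no reads in 1 group. A fitted fold change of such a gene depends on the prior count and is no bound on the fold. The remaining rows with a value lay outside both ranges and were not explained. On simulated data of 3000 genes, all 187 genes with lowered degrees of freedom and a usable F were recovered, with 0 false ones. The simulation used 2 fixed values of the degrees of freedom. It therefore checks the calculation only and does not measure false ones among the real rows.

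Because the table holds no values per library, the count model that had been chosen was not run and the authors' values were summarised as theirs, with the thresholds fixed beforehand: FDR under 0.05, and at least a 2-fold change where stated. The rules, the thresholds, the gene lists and the panel were chosen before the data were examined. The genes named in the text are the 10 protein-coding genes with the largest positive and the 10 with the largest negative fold change among those past the threshold with a mean log2 CPM of at least 2, a panel of 26 genes named whatever their result, and, for each described list, up to 3 members past the threshold in the direction most members took and up to 2 in the other, with a mean log2 CPM of at least 0. FGFBP2 has the form of a pseudogene symbol and was kept because the annotation calls it protein coding. Any other gene named in the text was chosen after its values were seen. Some genes that these rules select, and 1 test that needs such a gene, are not reported here.

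There were 36 gene lists with 1043 distinct genes, of which 878 were in the table. The median log2 fold change of each list with at least 5 members in the table was set against the medians of 10000 random lists of the same size, each member replaced by a gene of the same twentieth of mean expression (20 classes). The two-sided p was Benjamini-Hochberg adjusted over 35 lists. The smallest p that these random lists can give is 0.0002. The percentile and p describe these libraries, because genes are not independent replicates. The percentile had been planned as a description; the p, its adjustment and the calls from it were added once the files had been seen. As alternatives chosen after seeing the data, limma's cameraPR was run on the signed square root of the deposited F with the inter-gene correlation preset at 0.01 and at 0.05, random lists were drawn without matching, and genes with low expression or recovered as having no reads in 1 group were left out. A correlation estimated per list needs values per library and was not computed here. On simulated data of 15094 genes, the random-list test called 3.33% of 300 unshifted lists of 25 genes and 78.0% of lists shifted by 1. On simulated data of 15000 genes, cameraPR called 3.3% of unshifted sets at a correlation of 0.01, and 97.5% of shifted sets at 0.05. In both simulations the genes were independent of each other. These shares therefore do not measure false calls on lists whose members vary together.

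Families of genes were also tested within expression: each member was given the share of called genes among the other genes of its twentieth of mean expression, and the exact two-sided p of the count came from these shares. That test was chosen after seeing the data.

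Symbols were matched to GENCODE release 44 (GRCh38, the same assembly as hg38), directly or through older symbols in RefSeq: 14645 of 15108 rows (96.9%) matched, 277 of them by an older symbol. Coordinates are from that annotation, which may not be the authors' annotation. In 14 rows a spreadsheet program had turned the symbol into a date, and 2 dates each stand on 2 rows; these rows were kept in counts and left out of lists and matching. For each matched gene the GC content of 100 kb of DNA on each side, without the gene itself, was computed in bins of 1 kb, with the GC content and length of its canonical transcript. Relations along the genome were tested by 2000 circular shifts of the gene order, which keep neighbouring genes together. On simulated data of 14645 genes, 8 of 100 unrelated runs and 100 of 100 related runs had a p under 0.05, so these p-values can be somewhat too small. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.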

Results

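The data compare the transcriptome of IMR-32 neuroblastoma cells after 16 days of differentiation in 2.5 µM BrdU (3 libraries) with that of untreated IMR-32 cells (3 libraries), all carrying an empty lentiviral vector. The question, per the series labels, was how far the transcriptome changes when these cells differentiate. The values are those of the authors' deposited table, which gives per gene a log2 fold change, a mean log2 CPM and an FDR from the authors' edgeR test. The table's sign is not stated and was read as positive for genes higher in the BrdU-differentiated cells, from textbook neuronal genes, MYCN, LIN28B and DNA replication genes, so if it ran the other way every direction below would swap. The sequencing depth of the libraries is unknown. The labels give no time in culture for the untreated cells, so an effect of BrdU or differentiation cannot be told apart from one of time in culture.

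BrdU-differentiated cells had more genes higher than lower, and the decreases were shallower than the increases. Of 15108 genes in the authors' deposited table, 5300 (35.1%) passed an FDR of 0.05, with 3222 higher and 2078 lower in the BrdU-differentiated cells, and 6587 had an unadjusted p under 0.05. The median log2 fold change was 1.38 among the higher genes and -0.64 among the lower ones, while the median of all genes was 0.00075. At least a 2-fold change was found for 2054 higher and 398 lower genes in the authors' deposited table. With at least an 8-fold change the counts were 660 higher and 20 lower, and with at least a 32-fold change 209 and 3. Increases were most frequent among weakly expressed genes: in the fifth of genes with the lowest mean expression 32.8% were higher and 7.18% lower, against 12.8% and 16.6% in the fifth with the highest. No reads in 1 group were recovered for 140 genes of the authors' deposited table, of which 138 had a positive and 2 a negative fold change, and 111 were called higher and 0 lower.

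**Figure D1:**
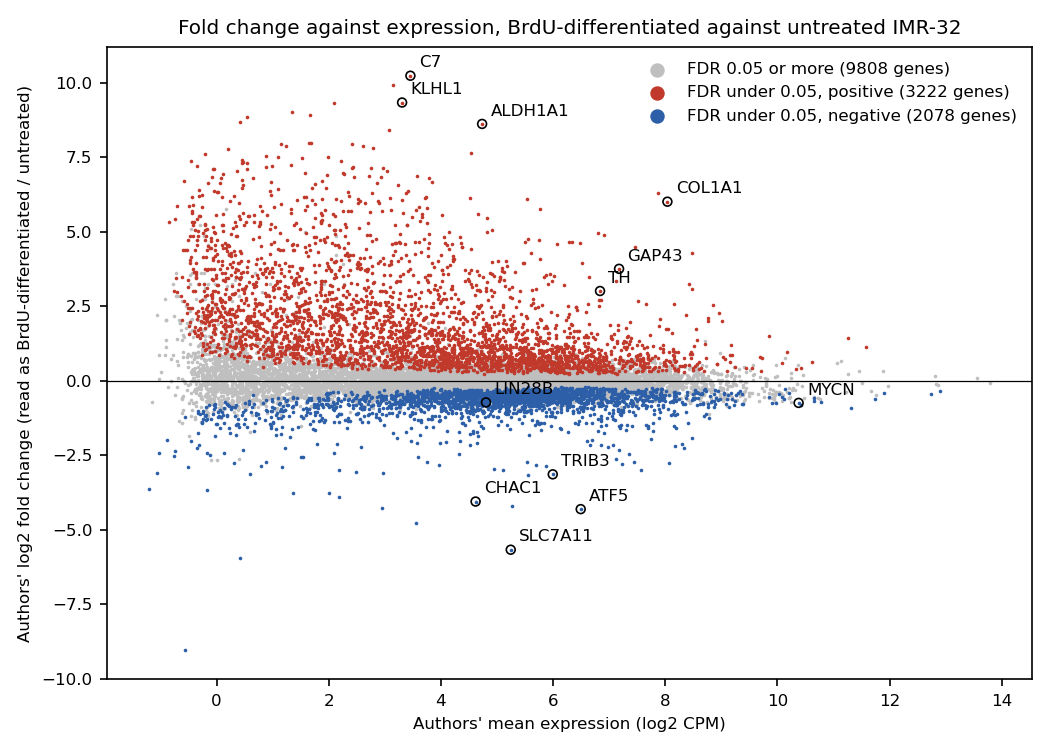
Each point is 1 of 15108 rows of the authors' deposited table, with the mean log2 CPM over the libraries on the x axis and the log2 fold change on the y axis, where positive is read as higher in BrdU-differentiated cells (the sign is not stated in the table). Red points (3222) and blue points (2078) have an FDR under 0.05, grey points do not, and circles mark named genes, from C7 at 10.23 to SLC7A11 at -5.68.

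The largest increases included genes of complement, retinoid metabolism, keratin filaments and calcium channels. In the authors' deposited table the highest log2 fold change with a mean log2 CPM of at least 2 was 10.23 for C7, a complement component gene (chromosome 5, 40909492 to 41020216, FDR 4.34e-07), followed by 9.93 for TMEM132C. ALDH1A1, which encodes a retinaldehyde dehydrogenase (chromosome 9, 72900671 to 73080442), had a log2 fold change of 8.61 with the lowest FDR of the increases named here, 5.75e-12, in the authors' deposited table. KLHL1 (9.33), FGFBP2 (9.33), PIRT (8.41), the keratin gene KRT17 (7.95), SCEL (7.89), the calcium channel subunit gene CACNA2D3 (7.81) and the axon guidance ligand gene SEMA3C (7.62) completed the 10 largest increases with that limit on expression in the authors' deposited table. C7, TMEM132C, FGFBP2 and KRT17 were recovered as having no reads in 1 group, so their fitted folds depend on the prior count and are no bounds.

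The largest decreases included genes of amino acid supply and the integrated stress response. SLC7A11, the cystine transporter gene (chromosome 4, 138164097 to 138242349), had the largest decrease among called protein-coding genes with a mean log2 CPM of at least 2 in the authors' deposited table, with a log2 fold change of -5.68 (FDR 7.44e-10). With the same limit on expression, the next in the authors' deposited table were AKNA (-4.78), the stress transcription factor gene ATF5 (-4.31), NIBAN1 (-4.29), the stanniocalcin gene STC2 (-4.19) and the glutathione-degrading enzyme gene CHAC1 (-4.06, chromosome 15, 40952962 to 40956512). KLHDC7B (-3.90), FUT1 (-3.76), PCK2, which encodes mitochondrial phosphoenolpyruvate carboxykinase (-3.15), and TRIB3 (-3.15) followed in the authors' deposited table. The list of 26 unfolded protein and integrated stress response genes had 0 members higher, 21 lower and 5 not past the threshold (21 lower also when adjusted over the list alone). Its median of -1.88 was below those of the 10000 random lists (adjusted p = 0.000538; central 95% of random medians -0.26 to 0.14).

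Genes of the catecholamine pathway and of neurite growth rose, and several are those from which the sign was read. Log2 fold changes in the authors' deposited table were 3.01 for TH (FDR 4.81e-06), which encodes the rate-limiting enzyme of catecholamine synthesis, and 2.03 for DBH, which makes noradrenaline. The vesicular monoamine transporter gene SLC18A1 (6.35), the monoamine oxidase gene MAOB (5.17) and CYB561 (4.47) rose most in that list of the authors' deposited table, while the chromogranin gene CHGA was at -0.13 (FDR 0.910). Of 19 catecholamine genes 10 were higher and 1 lower (10 and 1 adjusted over the list alone), with a median of 0.83 (adjusted p = 0.000538), or 0.52 with a mean log2 CPM of at least 1. Of 27 neuronal cytoskeleton and neurite genes 18 were higher and 1 lower (19 and 1 adjusted over the list alone), with a median of 0.77 (adjusted p = 0.000538). The synuclein gene SNCG (7.04), STMN4 (4.74), GAP43 (3.75), NEFL (1.83) and MAP2 (0.73) rose in the authors' deposited table, and NCAM1 fell (-0.47).

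Receptor genes for neurotrophic factors were among those that rose. NTRK2 (3.16), RET (2.68), its co-receptor gene GFRA1 (4.71), ERBB4 (4.30) and NRG1 (3.70) were higher in the authors' deposited table. BDNF (-1.56) and GFRA2 (-1.02) were lower in the authors' deposited table. Of 26 genes of this list 10 were higher and 2 lower (10 and 2 adjusted over the list alone; median 0.46, adjusted p = 0.00553), and the median was 0.31 with a mean log2 CPM of at least 1. The catecholamine, neurite and neurotrophic lists include genes used to read the sign and are no independent evidence of its direction. The same holds for the DNA replication list, the MYCN and MYC target list and the early developmental list, the last 2 of which contain LIN28B.

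Other neuronal lists, none of whose named genes served to read the sign, moved the same way. Of 14 cholinergic genes 9 were higher and 1 lower (11 and 1 adjusted over the list alone; median 1.48, adjusted p = 0.00219). The choline transporter gene SLC5A7 (7.38), CHRNA9 (4.12) and VIP (3.47) rose and the muscarinic receptor gene CHRM2 (-1.08) fell in the authors' deposited table. Of 27 voltage-gated ion channel genes 18 were higher and 3 lower (18 and 4 adjusted over the list alone; median 0.97, adjusted p = 0.000538), among them CACNA1E (5.63) and SCN7A (5.58) higher and CACNA2D1 (-0.81) and SCN8A (-0.43) lower in the authors' deposited table. Of 27 synaptic vesicle and release genes 14 were higher and 1 lower (17 and 1 adjusted over the list alone; median 0.75, adjusted p = 0.000538), with RAB3A (2.21), SYN3 (2.10) and SYN1 (1.58) higher and VAMP1 (-0.97) lower in the authors' deposited table. Axon guidance genes split, 18 of 41 being higher and 8 lower (18 and 8 adjusted over the list alone; median 0.23, adjusted p = 0.0073). EPHA3 (6.09) and the netrin receptor gene DCC (4.43) rose, and UNC5B (-1.52) and SEMA5A (-1.32) fell, in the authors' deposited table; the list was not called against unmatched random lists.

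The transcription factors of the noradrenergic identity did not rise with these genes. Of 22 listed factors 3 were higher and 11 lower (3 and 11 adjusted over the list alone), and the median of -0.36 was below the random lists (adjusted p = 0.0143). With cameraPR at a preset correlation of 0.05 this call was lost (adjusted p = 0.118). INSM2 (-1.19), SIX3 (-0.91) and HAND2 (-0.30, FDR 0.0364) were lower, and TFAP2B (1.05) and ZNF536 (0.83) higher, in the authors' deposited table. GATA3 was at -0.28 (FDR 0.635) and the receptor kinase gene ALK at -0.38 (FDR 0.481) in the authors' deposited table.

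Matrix, mesenchymal and glial genes rose alongside the neuronal ones. The collagen genes COL3A1 (6.29) and COL1A1 (6.0, FDR 2.20e-09) and the proteoglycan gene DCN (6.14) led the matrix list in the authors' deposited table, and FN1 rose by 2.0, while the laminin gene LAMB1 (-1.14) and NID1 (-1.06) fell. Of 46 matrix genes 23 were higher and 5 lower (25 and 6 adjusted over the list alone; median 0.72, adjusted p = 0.000538). Of 29 genes that mark the mesenchymal state of neuroblastoma cells 17 were higher and 4 lower (18 and 4 adjusted over the list alone; median 1.26, adjusted p = 0.000538). ANXA1 (6.58), PTPRC (5.72), MEOX1 (4.36), CD44 (1.88) and VIM (0.95) were higher in the authors' deposited table, whereas SNAI2 (-1.19) and ZEB1 (-1.13), which encode repressors of epithelial genes, were lower. MEOX1 was recovered as having no reads in 1 group, so its fitted fold is no bound. Of 18 Schwann and glial markers 14 were higher and 0 lower (14 and 0 adjusted over the list alone, median 1.49, adjusted p = 0.000538), among them FABP7 (5.74), EGR1 (2.90) and S100B (2.58) in the authors' deposited table. Of the 18, 6 also stand in other lists, EGR1 and EGR2 among them in the immediate early list, which can reflect handling of the cells. That list was called higher too, a call lost with cameraPR at a preset correlation of 0.05 (adjusted p = 0.142). SOX10, a panel gene that also stands in the glial list, was not among the genes of the authors' deposited table. The 18 markers counted are those present there of 22 written.

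Some markers of other cell types were higher as well, among those that could be tested. The authors' deposited table held 7 of 12 endothelial, 5 of 19 blood cell, 9 of 17 epithelial and 9 of 12 melanocyte markers. The others were absent from it. A marker silent in the untreated cells can be listed only if the BrdU-differentiated cells had reads of it. The counts below therefore lean towards higher and do not show that most markers of a cell type rose. KDR (4.59), ERG (5.20) and TEK (6.97) were higher in the authors' deposited table among 7 endothelial markers, of which 5 were higher and 0 lower (5 and 0 adjusted over the list alone; median 4.59, adjusted p = 0.00219). Without the 2 of these recovered as having no reads in 1 group the median was 3.34 and the call was kept, while with a mean log2 CPM of at least 1 fewer than 5 members were left and the list was not tested. TEK was recovered as having no reads in 1 group, so its fitted fold is no bound. PTPRC (5.72), LAPTM5 (4.81) and CORO1A (0.89) were the 3 higher of 5 blood cell markers in the authors' deposited table, with 0 lower (3 and 0 adjusted over the list alone; median 0.89, adjusted p = 0.344), and PTPRC also stands in the mesenchymal list. Both cameraPR settings called the blood cell list (adjusted p = 0.00474 and 0.0135). KRT19 (6.19), CDH1 (3.65) and KRT18 (2.47, FDR 0.0497) were higher in the authors' deposited table among 9 epithelial markers, of which 5 were higher and 0 lower (5 and 0 adjusted over the list alone; median 1.93, adjusted p = 0.0344), a call lost with cameraPR (adjusted p = 0.202 and 0.278). Of 9 melanocyte markers 6 were higher and 1 lower (6 and 1 adjusted over the list alone; median 0.93, adjusted p = 0.126), with TYRP1 (2.85), EDNRB (2.11) and OCA2 (1.96) higher and MITF (-0.94) lower in the authors' deposited table.

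**Figure D2:**
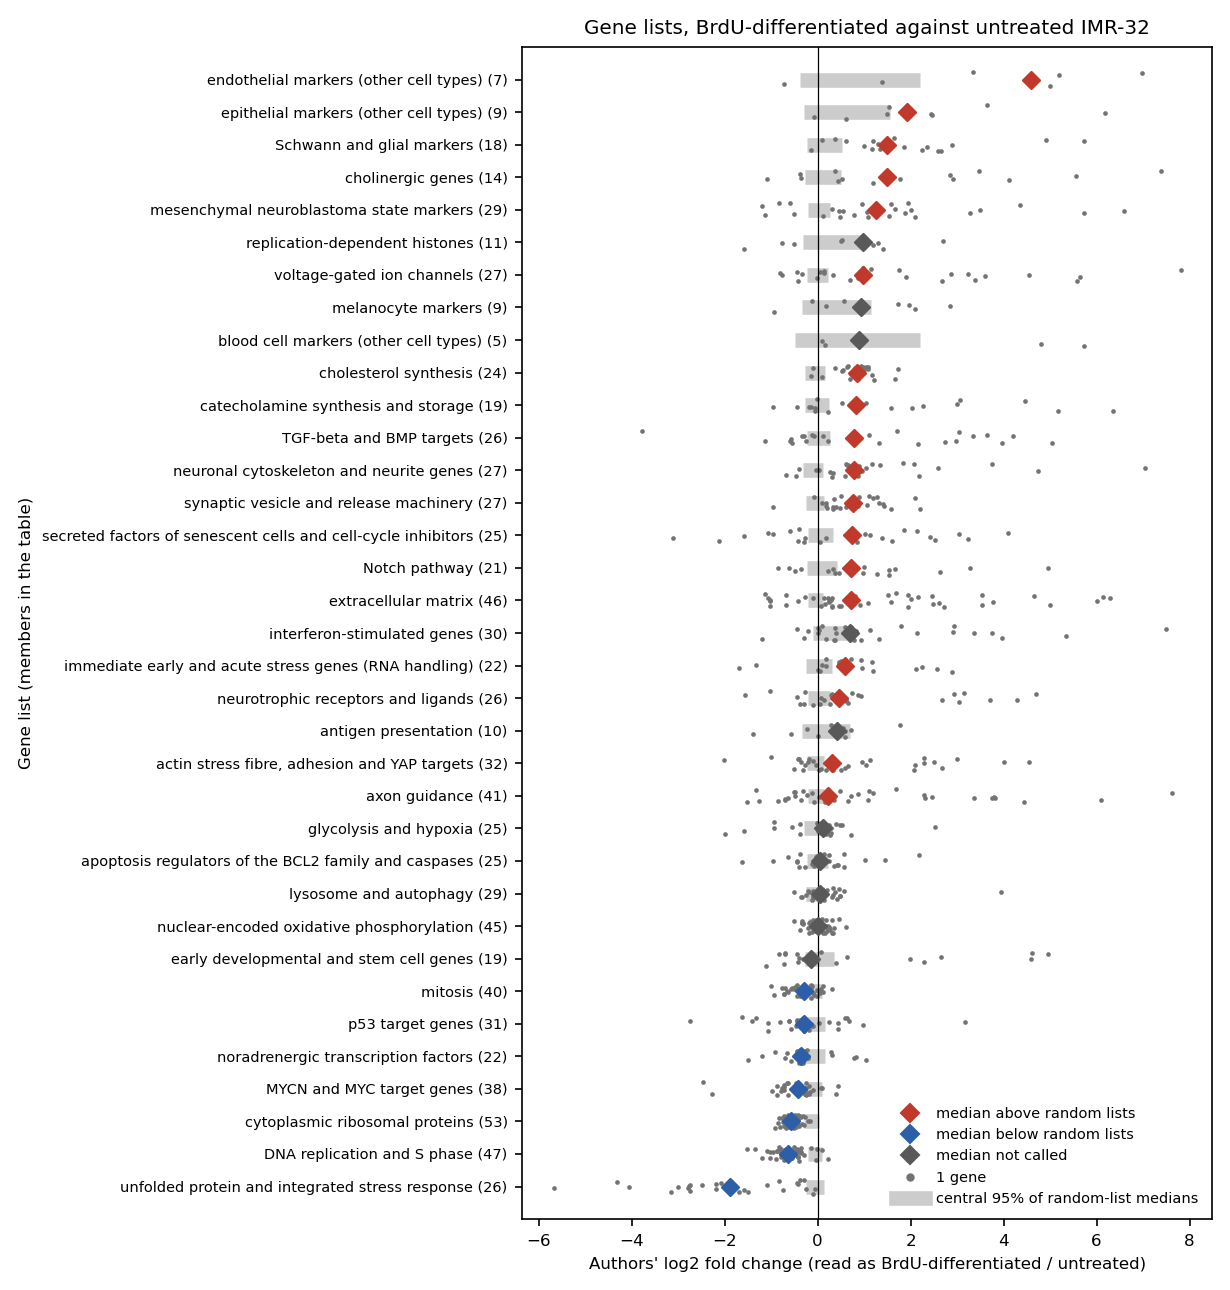
Log2 fold changes of the authors' deposited table (x axis, positive read as higher in BrdU-differentiated cells) for the members of 35 gene lists, 1 list per line. Small points are genes, diamonds are list medians (red for the 18 above and blue for the 7 below random lists at an adjusted p under 0.05, dark grey for the 10 not called), and grey bars span the central 95% of 10000 random lists matched on expression. Medians run from 4.59 for 7 endothelial markers to -1.88 for 26 stress response genes.

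Replication genes fell moderately, while proliferation markers of the panel did not pass the threshold. Of 47 DNA replication and S phase genes 0 were higher and 33 lower (37 lower adjusted over the list alone; median -0.64, adjusted p = 0.000538), with PRIM1 (-1.52), ORC1 (-1.35) and CCNE2 (-1.19) lowest among the named members in the authors' deposited table. Of 40 mitosis genes 0 were higher and 11 lower (10 lower adjusted over the list alone; median -0.28, adjusted p = 0.00567), with KIF2C (-1.0), HMMR (-0.77) and NUF2 (-0.73) in the authors' deposited table. The mitosis call was lost with cameraPR at a preset correlation of 0.05 (adjusted p = 0.0573). MKI67 was at -0.11 (FDR 0.527), TOP2A at -0.31 (FDR 0.253) and TK1 at 0.22 (FDR 0.421) in the authors' deposited table.

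MYCN, the amplified oncogene of this line (chromosome 2, 15940550 to 15947007), had a log2 fold change of -0.75 (FDR 0.0204) at a mean log2 CPM of 10.38 in the authors' deposited table. MYC, its paralogue, was higher (2.58, FDR 8.11e-05) at a mean log2 CPM of 2.24, and LIN28B was lower (-0.73) in the authors' deposited table. Of 38 MYCN and MYC target genes 0 were higher and 16 lower (16 lower adjusted over the list alone, median -0.42, adjusted p = 0.000538). They were led in the authors' deposited table by the one-carbon enzyme genes SHMT2 (-2.46) and MTHFD2 (-2.26) and by FBL (-0.99), a gene of ribosomal RNA modification. SHMT2 and MTHFD2 also belong to a family of serine, glycine and one-carbon enzymes that was lower in 11 of 17 cases, so their decrease is not particular to MYCN and MYC targets. Of 53 cytoplasmic ribosomal protein genes 0 were higher and 9 lower (7 lower adjusted over the list alone; median -0.57, adjusted p = 0.000538), with RPL4 (-0.92), RPS7 (-0.83) and RPL6 (-0.80) in the authors' deposited table. Ribosomal protein genes share sequence with many processed pseudogenes, so their values are uncertain where the counting split reads.

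Genes activated by p53 were lower on balance. CDKN1A (-1.06, FDR 7.94e-07) and MDM2 (-0.47), both classical targets, fell in the authors' deposited table, as did SESN2 (-2.74), PMAIP1 (-1.62) and TNFRSF10B (-1.42), while PLK2 (3.17) and BTG2 (0.97) rose. Of 31 targets 4 were higher and 13 lower (4 and 13 adjusted over the list alone, median -0.30, adjusted p = 0.007). Of the 31, 6 also stand in other lists, among them SESN2 in the stress response list, where 21 of 26 genes were lower. The list of secreted factors of senescent cells and cell-cycle inhibitors went both ways, with 11 of 25 higher and 7 lower (11 and 8 adjusted over the list alone; median 0.73, adjusted p = 0.002). IGFBP7 (4.10) and MMP1 (3.24) were higher and GDF15 (-3.11) and PLAUR (-2.13) lower in the authors' deposited table. With cameraPR this list was not called and leaned the other way (adjusted p = 0.999 at both correlations), and with a mean log2 CPM of at least 1 its median was 0.19 and the call was lost.

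Cholesterol synthesis genes rose together. Of 24 members 17 were higher and 0 lower (17 and 0 adjusted over the list alone; median 0.84, adjusted p = 0.000538), among them HMGCS1 (1.73) and DHCR7 (1.21) in the authors' deposited table. Of 21 Notch pathway genes 12 were higher and 2 lower (12 and 2 adjusted over the list alone; median 0.72, adjusted p = 0.00567), with DLK1 (4.96), NOTCH2 (3.29) and HES1 (2.63) higher and DLL3 (-0.85) and NRARP (-0.62) lower in the authors' deposited table. NOTCH2 has near-identical partial copies on chromosome 1, so its value is uncertain. Of 26 TGF-beta and BMP genes 12 were higher and 3 lower (13 and 4 adjusted over the list alone; median 0.79, adjusted p = 0.000538), a call lost with cameraPR (adjusted p = 0.0824 and 0.222). BMP5 (5.05), TGFBI (3.97) and LEFTY2 (3.65) were higher and INHBE (-3.77) and BAMBI (-1.13) lower in the authors' deposited table. Of 32 actin, adhesion and YAP target genes 12 were higher and 3 lower (12 and 3 adjusted over the list alone; median 0.31, adjusted p = 0.00288), a call also lost with cameraPR (adjusted p = 0.479 and 0.648), with CCN2 (4.55), ACTG2 (4.01) and ITGA5 (2.99) higher and AJUBA (-2.02) and CNN2 (-1.01) lower in the authors' deposited table. Immediate early and acute stress genes, a list kept as a sign of handling before RNA isolation, were higher in 11 of 22 cases and lower in 2 (12 and 2 adjusted over the list alone; median 0.58, adjusted p = 0.00428), with EGR1 (2.90), MYC (2.58) and EGR2 (2.25) higher and ATF3 (-1.70) and NR4A1 (-1.33) lower in the authors' deposited table. That call was lost with cameraPR at the larger correlation (adjusted p = 0.142).

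The next lists were not called against matched random lists. Of 30 interferon-stimulated genes 16 were higher and 1 lower (16 and 2 adjusted over the list alone; median 0.70, adjusted p = 0.0587), with IFI44 (7.50), BST2 (5.33, recovered as having no reads in 1 group, so no bound) and IFIT3 (3.97) higher and ISG20 (-1.19) lower in the authors' deposited table. CameraPR called this list at a correlation of 0.01 (adjusted p = 0.00616) and not at 0.05 (adjusted p = 0.0585), and it was called against unmatched random lists and with a mean log2 CPM of at least 1. Of 10 antigen presentation genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.25), with NLRC5 (1.77) and B2M (0.59) higher in the authors' deposited table. Of 11 replication-dependent histone genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.062), with HIST2H2BE (2.70), HIST1H2BD (1.40) and HIST1H2AC (1.30) higher and HIST1H4C (-1.57) lower in the authors' deposited table; histone genes are near-identical to each other, so these values are uncertain. The histone list was called against unmatched random lists (median 0.97) and with a mean log2 CPM of at least 1 (median 1.20). Early developmental genes split into 7 higher and 7 lower of 19 (7 and 7 adjusted over the list alone; adjusted p = 0.323), with DLK1 (4.96), IGF2 (4.61) and H19 (4.58) higher and SALL4 (-1.11) and IGF2BP1 (-0.82) lower in the authors' deposited table. The median of that list was -0.15 and its mean 0.86; with a mean log2 CPM of at least 1 the median was -0.31 and the list was called.

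Metabolic and survival lists without a call were mixed. Oxidative phosphorylation genes had 0 of 45 members higher and 2 lower (0 and 1 adjusted over the list alone; adjusted p = 0.21), among them CYC1 (-0.31) in the authors' deposited table. Glycolysis and hypoxia genes had 6 of 25 higher and 6 lower (6 and 6 adjusted over the list alone; adjusted p = 0.101), with EGLN3 (2.52), ALDOC (0.71) and HK1 (0.52) higher and VEGFA (-2.0) and HK2 (-1.58) lower in the authors' deposited table. Lysosome and autophagy genes had 5 of 29 higher and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.255), with GABARAPL1 (3.95), ATP6V1H (0.48) and SQSTM1 (0.42) in the authors' deposited table. Apoptosis regulators had 3 of 25 higher and 5 lower (3 and 5 adjusted over the list alone; adjusted p = 0.468), with BIRC3 (2.18) higher and PMAIP1 (-1.62), HRK (-0.97) and BCL2 (-0.63) lower in the authors' deposited table. Mitochondrially encoded mRNAs had 0 members among the genes used and were not analysed here.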

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

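Positive fold changes are read as higher in BrdU-differentiated cells, and all alternative settings for gene lists, those leaving out genes with no reads in 1 group and the expression limit for named genes were chosen after seeing the data. An FDR of 0.01 gave 1268 lower genes in place of 2078. Requiring at least 1.5-fold gave 1192 lower genes, and 3953 genes in place of the 2452 that changed at least 2-fold. Requiring at least 4-fold gave 1209 genes in all, 1135 higher and 74 lower. The other settings of these counts, and those of the named genes, stayed within 1.5 times of the reported counts. These counts differ because fewer or more genes meet the stricter or looser limit.

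Of 25 lists called, 18 were also called in the same direction under both cameraPR settings, and 0 were called in the opposite direction under any setting. The senescence factors had the opposite direction with cameraPR, without a call. Adjusted p rose past 0.05 with cameraPR at a correlation of 0.05 for noradrenergic factors (0.118), mitosis (0.0573) and immediate early genes (0.142). At correlations of 0.01 and 0.05 it did so for actin and YAP targets (0.479 and 0.648), senescence factors (0.9992 and 0.9994), TGF-beta and BMP targets (0.0824 and 0.222) and epithelial markers (0.202 and 0.278). CameraPR added blood cell markers (0.00474 and 0.0135) and, at 0.01, interferon-stimulated genes (0.00616). With unmatched random lists the calls of melanocyte markers (median 0.93), interferon-stimulated genes (0.70) and histones (0.97) were gained and that of axon guidance (0.23) lost. With a mean log2 CPM of at least 1, interferon-stimulated genes (0.70), histones (1.20) and early developmental genes (-0.31) gained a call, senescence factors (0.19) lost theirs, and endothelial and blood cell markers fell under 5 members and were not tested. The causes were not tested.

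No paired analysis was possible because the table holds no values per library. For the same reason the planned other normalizations, count filters, DESeq2, voom and glmTreat fits, camera with an estimated correlation, fry, leaving out each library and library composition were not run, and the depth limit on weakly expressed genes is unknown.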

Other observations

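The families in this paragraph and the next were chosen after the values were seen, 15 families in all with 30 Fisher's exact tests (two-sided) against the other genes, repeated against genes of the same expression class, as weakly expressed genes rose more often, and positive again means higher in BrdU-differentiated cells. Ionotropic and metabotropic glutamate receptor genes were higher in 17 of 24 cases and lower in 1 (adjusted p = 2.73e-06; 4.36e-05 within classes). GABA receptor genes were higher in 8 of 15 cases and lower in 0 (adjusted p = 0.0191), a call lost within classes (4.27 expected, adjusted p = 0.211). GRIA1 (3.59), GRIN2A (4.73) and GABRA4 (5.10) rose in the authors' deposited table. Complement genes were higher in 8 of 12 cases and lower in 1 (adjusted p = 0.00455; 3.20 higher expected within classes, adjusted p = 0.0351), with CLU, which encodes clusterin, at 3.23 and a mean log2 CPM of 8.42 in the authors' deposited table. C6, C7 and CFI in that family were recovered as having no reads in 1 group, so their fitted folds are no bounds, and some members of the family share sequence and are uncertain. Guanylate-binding protein genes, a family induced by interferon, were higher in 5 of 6 cases (adjusted p = 0.00929; lost within classes, 0.0983), with GBP2 at 4.81 and a mean log2 CPM of 4.05 in the authors' deposited table; these genes also share sequence.

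Cytosolic aminoacyl-tRNA synthetase genes, which encode the enzymes that charge tRNAs, were lower in 14 of 17 cases and higher in 0 (adjusted p = 5.69e-09), from CARS (-2.23) and GARS (-1.95) to QARS (-0.52) in the authors' deposited table. Serine, glycine and one-carbon enzyme genes were lower in 11 of 17 and higher in 1 (adjusted p = 1.36e-05), with ALDH1L2 at -2.88 and CTH at -2.85 in the authors' deposited table. Amino acid transporter genes were lower in 15 of 32 and higher in 4 (adjusted p = 3.83e-05), while the median of the family was -0.011. SLC7A11 and SLC7A5 of this family, and PHGDH and PSAT1 of the enzyme family, also stand in the stress response list. These counts therefore partly restate the decrease of that list. Zinc finger genes with a ZNF symbol, most of them transcriptional repressors, were higher in 24 of 439 cases, less often than other genes (adjusted p = 2.25e-19), and lower in 81 (adjusted p = 0.0163; lost within classes, 0.0676). Clustered protocadherin genes were higher in 15 of 41 cases, which missed the threshold (adjusted p = 0.0597), and lower in 0, less often than other genes (adjusted p = 0.0163; lost within classes, 0.0983); they share exons and are uncertain. The other families were HOX genes (2 of 8 higher, adjusted p = 0.757), keratins (6 of 13, 0.0845), claudins (3 of 7, 0.286), annexins (4 of 9, 0.195), matrix metalloproteinases (5 of 10, 0.0845) and semaphorins (9 of 22, 0.0804). The other calls in this paragraph were kept within classes.

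Among the 14645 matched genes, those that rose followed each other along the genome more often than in permutations. Of 14621 pairs of consecutive matched genes, 470 had both members past the threshold and at least 2-fold higher. Permuting the 2000 such genes gave a mean of 272.3 pairs (p = 0.0005, the smallest that 2000 permutations can give). Among 12167 pairs whose gene bodies do not overlap the counts were 416 and 226.3. Permuting within classes of flanking GC content and expression raised the expected number to 306.1. The same was seen for the 375 genes at least 2-fold lower, with 28 pairs against 9.57. Genes outside the table were skipped and no limit on distance was set, so the members of a pair need not be direct neighbours. Families that share sequence, such as clustered protocadherins and guanylate-binding proteins, were left in. The cause was not tested. This test of pairs was chosen after the values were seen.

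In this paragraph the partial rho with flanks of 100 kb and the ratio of shares were fixed before their results were seen, and the other settings and tests were chosen after seeing the data. Genes in AT-rich surroundings rose more often. In the fifth of genes with the lowest GC content in the 100 kb on each side (32.9% to 40.2%), 23.5% were past the threshold and at least 2-fold higher (Wilson 95% interval 22.02% to 25.1%), against 10.2% (9.13% to 11.3%) in the fifth with the highest. These intervals treat genes as independent, although matched genes that follow each other along the genome rose together more often than in permutations. They are therefore too narrow and measure no spread between libraries. If GC or length bias of the libraries were the whole cause, the relation would vanish given transcript GC, transcript length and expression. The partial Spearman rho across genes was -0.14 (-0.148 for genes with a mean log2 CPM of at least 2, circular-shift p = 0.0005, the smallest possible). This argues against bias acting through these measures of 1 canonical transcript per gene as the whole cause. Bias that they do not capture is left open. Low expression as the whole cause is argued against by the ratio of shares within 10 classes of expression, 2.16 (random 95% range 0.773 to 1.33). Activation of genes in AT-rich DNA, where more thymidine sites could take up BrdU, is a candidate explanation that this rho of -0.14 would allow, as a hypothesis only. The tissue-restricted genes that differentiation activates may lie in AT-rich DNA for other reasons, which was not tested, and transcript GC itself went the other way given the flanks (rho 0.19). The rho was -0.137 with flanks of 50 kb, -0.148 with 200 kb, -0.168 with 1 gene per 1 Mb and -0.127 with gene length added. Without any adjustment it was weaker, -0.048.

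The test of genes with no reads in 1 group was chosen after the result was seen. Of the 140 genes, 138 had a positive fold change in the authors' deposited table. Shallower libraries of the untreated cells could leave weakly expressed genes without reads: 99 of the 140 lay at or under the 10th percentile of mean log2 CPM (0.78), and 13 lay 1 log2 unit or more above it, up to 3.46 for C7, which neither bears out nor excludes this. The authors' edgeR test, which takes library totals into account, called 111 of the 140 higher and 0 lower. This argues against shallower libraries as the whole cause for these 111, although many of the 140 lay near the floor. For the rest, shallower libraries are left open. Cells of another type in the cultures and activation of silent genes during differentiation cannot be told apart here, and no test of either is reported.

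For the decrease of amino acid response genes, the test of normalization was chosen after the result was seen and that of endoplasmic reticulum stress before. The 14 members of the stress list other than 12 chaperone and folding genes are called amino acid response genes here. That name is a label for the remaining members, general integrated stress response genes among them, and points to no cause. These 14 had a median of -2.75 (bootstrap 95% interval -3.15 to -2.17) and all 14 were lower. Stress of the endoplasmic reticulum in the untreated cultures would be expected to raise the 12 chaperone and folding genes there as well. Their median was -0.43 (-0.95 to -0.26), with 7 lower and 0 higher, the direction that this cause predicts. It missed the 2-fold decrease set beforehand for this cause and met the limit set against it. A smaller decrease in the same direction cannot separate the causes, so such stress is left open. Both intervals resample genes, not libraries. XBP1 and HERPUD1, both at -2.18 in the authors' deposited table, fell with the response genes. The difference of -2.76 from the median of all genes met the value set against a shift from the authors' normalization, but that test decides nothing: normalization centres the median of all genes near 0, so the difference restates the decrease relative to other genes, and a shift of all genes together is left open. A difference in amino acid supply or cell density between the cultures remains a possible explanation, untested, as does the differentiation itself.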
